A study of Homo sapiens with 8 samples.

How the data were processed

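RNA was sequenced from 8 samples of IMR90 lung fibroblasts with hTERT, 2 in each combination of genotype (wild-type, ABCA1 knockout) and state (proliferating, senescent after bleomycin). Groups and replicate numbers were taken from the sample titles. Libraries were made with the TruSeq Stranded mRNA kit and sequenced on a NovaSeq instrument, per the labels' protocols. The deposited table holds raw read counts per gene, 1 column per library, which the authors made with Trimmomatic 0.36, HISAT2 2.1.0 and featureCounts 1.6.3 on hg38, per the submitters' processing notes. The gene annotation, the strand setting of the counting and any filters are not given in the sources used here, so counts of genes overlapping on opposite strands, and of near-identical copies, are uncertain.

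The table has 28395 gene IDs, of which 27745 were matched to a symbol through the RefSeq gene table of assembly GRCh38.p14. The 650 others held between 0.0524% and 0.0601% of a library's counts. Library totals ran from 28160545 to 38531137 counts. The position of ABCA1 comes from GENCODE release 29 on GRCh38.

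Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr on the groups (14392 genes), scaled with TMM and fitted with a quasi-likelihood model with 1 mean per group over all 8 libraries (robust, legacy off), which leaves 4 residual degrees of freedom. The common biological coefficient of variation was 10.5%. There were 5 comparisons: senescent against proliferating in each genotype, knockout against wild-type in each state, and the interaction. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05 with no minimum fold. The standard error of a log2 fold change was derived from its F statistic. A gene with no count in a group got a lower bound for its fold from a floor of 3 counts over the group, and one with 1 to 3 counts a Clopper-Pearson interval of the ratio, both covering counting error only, since reads without molecular identifiers are not independent molecules.

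The 18 pathway lists and 4 lists of cell type markers were fixed before the data were examined. Each pathway list was tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with an inter-gene correlation preset at 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison, and again with the correlation estimated for each list, with camera on ranks and with fry. List counts of calls rest on the adjustment over all genes tested unless stated as adjusted over the list alone. Genes named in the text follow a rule fixed beforehand. It takes ABCA1 and, in each comparison, the 6 called genes with the largest rise and the 6 with the largest fall, with a mean of at least 5 CPM in the higher group and, outside the interaction, no overlap between the libraries of the groups. Symbols in the style of clones, uncharacterized loci, long non-coding, antisense or pseudogenes were left out. It adds the called member of each list with the largest rise and the one with the largest fall, up to 3 members of a list by smallest p, and 34 core genes, of which 33 passed the filter. The remaining core gene, ABCG1, did not. The text names a subset of the genes this rule gives, chosen after their values and stability were seen. Some genes that the rule gives are not reported here.

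The fits were tested on counts of the 14392 genes simulated from the data's means, dispersions and library sizes. In each comparison 200 genes were changed by a known fold, fewer than were called in the data, where recovery may differ. In the wild-type response, 43.3% of 1.5-fold, 73.1% of 2-fold and 98.5% of 4-fold changes were recovered with the right sign. The knockout response gave 38.8%, 70.1% and 90.9% and proliferating genotypes 40.3%, 73.1% and 92.4%. Senescent genotypes gave 46.3%, 79.1% and 89.4% and the interaction 10.4%, 52.2% and 81.8%. In the same order, calls of unchanged genes were 10 of 153, 8 of 141, 9 of 146, 13 of 156 and 12 of 108. Each share exceeded the 5% aimed at. A simulated 1.5-fold rise of the p53 list in wild-type cells was called by camera, with 0 of the 17 other lists. Genes were drawn independently, so this says nothing of false list calls where the genes of a list vary together.

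The labels give each group replicates 1 and 2 without saying what a number marks. Replicate 2 minus 1 differences in log2 CPM correlated across 9447 genes in all 6 pairs of groups. With r of 0.52 and 0.62 within and 0.13 to 0.39 between genotypes, over 4 differences, pairing by number is uncertain. It was taken from the data, not the labels, before calls were compared. The fit with the replicate number as a block (the replicate block) is an alternative, and its value is given beside a result where it changed the call or moved a count by over 1.5 times. List counts without 1 library are given where they moved by as much and the larger was at least 3. The counts of replicate pairs differed by more than sampling noise (chi-square per degree of freedom 9.37 in proliferating wild-type, 47.2 in proliferating knockout, 18.8 in senescent wild-type and 17.7 in senescent knockout), so no library was counted as a duplicate. Other alternatives were DESeq2 1.42.0, limma-voom, edgeR's legacy dispersion, RLE, upper quartile and library total scaling, no filter or a filter at a mean of 5 CPM, removal of mitochondrially encoded genes, fits on only the groups compared, other thresholds, and leaving out each library in turn with the genes tested held fixed. Holding them fixed was chosen after the first fits without 1 library were seen. Corrections for GC content were added after the data were seen. Shares of counts and sums of marker genes were compared with two-sided exact permutation tests of 4 against 4 libraries, adjusted over 8 measures for each factor. They were repeated with libraries exchanged only within the other factor, with and without pairing by replicate number, a choice made after the data were seen.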

Results

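Gene expression was measured by RNA sequencing in IMR90 cells, a human lung fibroblast line, here carrying hTERT, the catalytic subunit of telomerase. The series holds 8 libraries in 4 groups of 2. Wild-type and ABCA1 knockout cells were each either left proliferating or made senescent with bleomycin, a drug that breaks DNA. ABCA1 moves cholesterol and phospholipid out of the cell onto apolipoproteins. Cells were kept in 3% oxygen with 15% serum, and the senescent groups received 10 µg/ml bleomycin for 24 h. The sample labels place the harvest 10 days after bleomycin and the series design text 7 days after it, so the time point is uncertain. The deposited counts summed to 31291003 and 30454604 in the proliferating wild-type libraries and to 32014939 and 34819785 in the proliferating knockout libraries. They summed to 32350820 and 38531137 in the senescent wild-type and to 37878985 and 28160545 in the senescent knockout libraries. Among the genes in the table, 14392 passed the count filter and were tested in each of 5 comparisons. Levels are CPM, counts scaled by library total and TMM factor, given as mean ± SD with n = 2 libraries per group. Log2 fold changes are given ± SE from edgeR's quasi-likelihood fit, in parentheses after the gene. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

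The targeted gene was examined first, as a check of the labels. ABCA1 (gene ID 19) lies on the minus strand of chromosome 9, from 104781002 to 104928237 in GRCh38, and is annotated as protein-coding. Its level was 24.3 ± 0.187 CPM in proliferating wild-type cells and 5.08 ± 2.06 in proliferating knockout cells (SD, n = 2 each). In senescent cells it was 98.3 ± 16.1 CPM in wild-type and 19.6 ± 0.0179 in knockout (SD, n = 2 each). Raw counts were 788 and 809, 206 and 128, 3302 and 3292, and 716 and 552 in the same order. The knockout libraries were lower in both states, with a log2 fold change of -2.27 ± 0.21 in proliferating cells (edgeR adjusted p = 3.56e-05) and -2.33 ± 0.19 in senescent cells (edgeR adjusted p = 6.29e-06). ABCA1 transcript rose after bleomycin in both genotypes, by 2.02 ± 0.19 in wild-type and 1.96 ± 0.21 in knockout cells. The interaction of -0.06 ± 0.28 did not pass the test (edgeR adjusted p = 0.940). The labels do not give the edited position, and transcript counts say nothing of the protein.

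**Figure D1:**
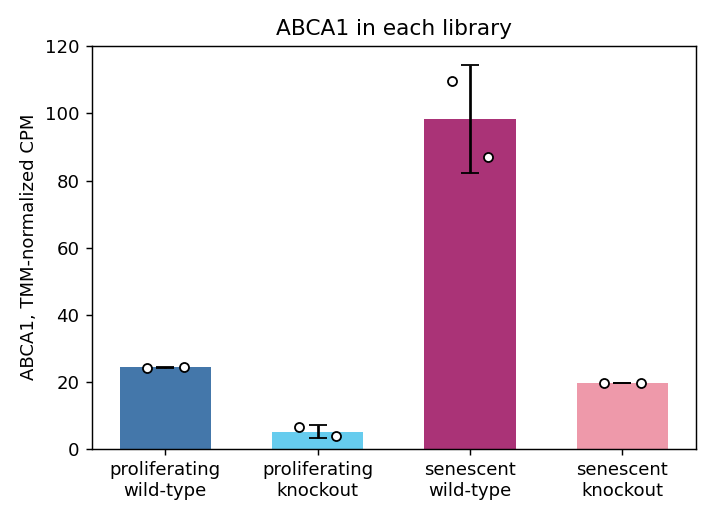
ABCA1 level in TMM-normalized CPM (y axis) in the 4 groups (x axis); bars are means, error bars SD and open circles the 2 libraries of each group. The knockout libraries lie at 6.53 and 3.62 CPM before bleomycin and at 19.6 and 19.6 after it, against 24.2 and 24.4, and 109.7 and 87.0, in wild-type cells.

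The first comparison asked how wild-type cells changed with bleomycin-induced senescence. Antiviral genes such as BST2, cytokine genes such as IL6 and the p53 target CDKN1A rose, and the proliferation genes MKI67 and LMNB1 fell. BST2, an antiviral membrane protein, went from 0.472 ± 0.0267 to 113 ± 1.34 CPM (7.89 ± 0.22). MX1, an antiviral GTPase, rose by 6.77 ± 0.19, IFI6 by 5.97 ± 0.14 and IFIT1 by 4.94 ± 0.19. The cytokine IL1A rose by 5.56 ± 0.26, CSF2 by 5.37 ± 0.32, IL1B by 3.62 ± 0.19 and IL6 by 3.55 ± 0.12. The chemokine CXCL8 rose from 17.7 ± 1.98 to 75.6 ± 15.6 CPM (edgeR adjusted p = 4.10e-07). CDKN1A, which encodes the p21 inhibitor of cyclin-dependent kinases, rose by 1.85 ± 0.10 and reached 1079.6 ± 22.6 CPM. MKI67, a proliferation marker, fell by 2.52 on the log2 scale and LMNB1, the lamin lost from senescent nuclei, fell by 2.59. Falls were also seen for ID1 (-3.52 ± 0.19), an inhibitor of bHLH transcription factors, and SOX11 (-3.38 ± 0.15).

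Among the gene lists fixed beforehand, interferon-stimulated genes had the largest median log2 fold change in wild-type cells, 4.32: 35 of 36 rose, or 35 adjusted over the list alone (camera adjusted p = 1.85e-29, and adjusted p = 0.0547 with an estimated correlation). Among the secreted cytokines and chemokines, 14 of 17 rose and 2 fell, or 14 and 2 adjusted over the list alone (camera adjusted p = 1.04e-05, and adjusted p = 0.0797 with an estimated correlation). A fall was that of CXCL12 (-1.69 ± 0.14). Among the secreted proteases and growth factors, 25 of 32 rose and 1 fell, or 26 and 1 adjusted over the list alone (camera adjusted p = 1.33e-08, and adjusted p = 0.0547 with an estimated correlation). Examples were ANGPTL4 (3.98 ± 0.15), IGFBP3 (2.73 ± 0.12) and the plasminogen activator PLAT (2.68 ± 0.13). Among the NF-kB feedback genes, 12 of 15 rose, or 12 adjusted over the list alone (camera adjusted p = 6.89e-07, and adjusted p = 0.0221 with an estimated correlation). They included the adhesion molecule ICAM1 (3.84 ± 0.13), TNFAIP3 (2.07 ± 0.13) and SOD2 (1.80 ± 0.11). Among the p53 targets, 26 of 32 rose, or 27 adjusted over the list alone (camera adjusted p = 2.96e-11, and adjusted p = 0.0127 with an estimated correlation). Named members were GDF15 (3.36 ± 0.17), BTG2 (2.66 ± 0.17) and MDM2 (0.85 ± 0.10), the last encoding the ubiquitin ligase of p53. The kinase inhibitors CDKN2A and CDKN2B rose by 1.04 ± 0.14 and 1.02 ± 0.16.

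Among the mitosis genes, 43 of 43 fell, or 43 adjusted over the list alone (camera adjusted p = 1.56e-31, and adjusted p = 0.00254 with an estimated correlation). Examples were CDC20 (-2.41 ± 0.10) and CCNA2 (-2.30 ± 0.10). Among the replication genes, 39 of 40 fell and 1 rose, or 39 and 1 adjusted over the list alone (camera adjusted p = 2.47e-26, and adjusted p = 0.0221 with an estimated correlation). They included MCM2 (-2.06 ± 0.12) and MCM7 (-2.15 ± 0.11). Among the nuclear proteins lost in senescence, 10 of 10 fell, or 10 adjusted over the list alone (camera adjusted p = 3.43e-10, and adjusted p = 0.0221 with an estimated correlation). An example was HMGB2 (-2.23 ± 0.13). Among the cholesterol synthesis and uptake genes, 14 of 24 fell and 1 rose, or 15 and 1 adjusted over the list alone (camera adjusted p = 2.19e-05, and adjusted p = 0.0408 with an estimated correlation). Falls in that list included the sterol-responsive regulator INSIG1 (-1.31 ± 0.11) and HMGCS1 (-0.57 ± 0.10), and the rise was TM7SF2 (1.11 ± 0.18). Among the fatty acid synthesis genes, 8 of 14 fell and 2 rose, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0144, and adjusted p = 0.369 with an estimated correlation). Named members were SCD (-1.52 ± 0.12) and FASN (-1.32 ± 0.15).

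Among the lysosomal genes, 30 of 38 rose and 1 fell, or 31 and 2 adjusted over the list alone (camera adjusted p = 1.33e-08, and adjusted p = 0.145 with an estimated correlation). They included CTSK (1.42 ± 0.10), GAA (1.40 ± 0.12) and GLB1 (0.85 ± 0.11), the gene behind senescence-associated galactosidase activity. In the same libraries the summed leukocyte markers, mostly the lysosomal protein CD68, were 98.1 CPM against 54.5 before bleomycin. Among the fibrillar matrix genes, 18 of 28 rose and 1 fell, or 19 and 1 adjusted over the list alone (camera adjusted p = 7.62e-06, and adjusted p = 0.298 with an estimated correlation). An example was the crosslinking enzyme LOX (2.34 ± 0.14). Among the contractile and YAP target genes, 12 of 18 rose and 2 fell, or 12 and 2 adjusted over the list alone (camera adjusted p = 0.00658, and adjusted p = 0.122 with an estimated correlation). Among the ATF4 targets, 15 of 28 rose and 3 fell, or 15 and 3 adjusted over the list alone (camera adjusted p = 0.00386, and adjusted p = 0.0547 with an estimated correlation). Among the unfolded protein response genes, 7 of 20 rose, or 6 adjusted over the list alone (camera adjusted p = 0.0234, and adjusted p = 0.369 with an estimated correlation). Among the targets of the sterol receptor LXR other than ABCA1, 5 of 9 rose and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0126, and adjusted p = 0.108 with an estimated correlation). An example was APOE (3.49 ± 0.27). Caveolae genes and nuclear genes of oxidative phosphorylation did not pass the list test (camera adjusted p = 0.880 and 0.631), and CAV1 stood at 0.08 ± 0.12 (edgeR adjusted p = 0.613). Without proliferating wild-type replicate 2, 3 unfolded protein genes were called higher and the unfolded protein list was not called (camera adjusted p = 0.109). With proliferating knockout replicate 1 left out, 5 ATF4 target genes were called lower. When senescent wild-type replicate 1 was left out, 3 unfolded protein genes were called higher and the unfolded protein list was not called (camera adjusted p = 0.145). With the replicate block, 2 lysosomal genes, 2 fibrillar matrix genes and 5 ATF4 target genes were called lower. The unfolded protein list was not called with library totals alone (camera adjusted p = 0.0575).

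In all, 6683 of 14392 genes were called in wild-type cells at an edgeR adjusted p under 0.05, 3601 of them higher and 3082 lower. Scaling by library totals alone moved the median log2 fold change of all genes by -0.15 and gave 2617 higher and 4283 lower, so directions of small changes are relative to the scaling.

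The second comparison asked the same of knockout cells. MKI67 and LMNB1 fell and BST2 and CDKN1A rose, as in wild-type cells. Among the cytokines and chemokines, 4 of 17 rose and 3 fell, or 4 and 3 adjusted over the list alone, and the list was not called (camera adjusted p = 0.336). MKI67 fell from 206 ± 48.0 to 12.1 ± 1.64 CPM (-4.08 ± 0.18). Falls were also seen for CDC20 (-4.22 ± 0.12), LMNB1 (-4.34 ± 0.15), HMGB2 (-3.06 ± 0.14) and the ribonucleotide reductase subunit RRM2 (-3.76 ± 0.12). OAS1 rose by 4.60 ± 0.20, BST2 by 4.47 ± 0.18, MX1 by 4.45 ± 0.16 and IFIT1 by 3.40 ± 0.17. CDKN1A rose by 1.45 ± 0.10, MDM2 by 0.69 ± 0.10, GDF15 by 2.48 ± 0.19 and CDKN2A by 0.69 ± 0.13. IL6 rose by 0.63 ± 0.11 and IL1A by 2.97 ± 0.33. IL1B stood at 0.23 ± 0.29 (edgeR adjusted p = 0.550) and CCL2 at 0.48 ± 0.29 (edgeR adjusted p = 0.201). CSF2 stood at 0.82 ± 0.38 (edgeR adjusted p = 0.0997) and was called without proliferating knockout replicate 2 (1.53, edgeR adjusted p = 0.0144) and without senescent knockout replicate 1 (1.20, edgeR adjusted p = 0.0404). CXCL8 was called at -0.44 ± 0.15 (edgeR adjusted p = 0.0395) but lost the call when any 1 of 6 libraries was left out. The edgeR adjusted p was 0.0648 and 0.0647 without proliferating wild-type replicate 1 or 2, 0.0527 and 0.0706 without proliferating knockout replicate 1 or 2, and 0.159 and 0.0722 without senescent knockout replicate 1 or 2. With all libraries, CXCL8 was not called with upper quartile scaling (edgeR adjusted p = 0.0605), library totals alone (0.0601), a mean of at least 5 CPM per gene (0.0612), the GC correction (0.122) or limma-voom (adjusted p = 0.0543).

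Among the mitosis genes in knockout cells, 43 of 43 fell, or 43 adjusted over the list alone, with a median log2 fold change of -3.71 (camera adjusted p = 7.96e-44, and adjusted p = 0.00131 with an estimated correlation). Among the replication genes, 39 of 40 fell and 1 rose, or 39 and 1 adjusted over the list alone (camera adjusted p = 6.52e-32, and adjusted p = 0.0190 with an estimated correlation), and of the nuclear proteins lost in senescence 10 of 10 fell, or 10 adjusted over the list alone (camera adjusted p = 3.28e-11, and adjusted p = 0.0190 with an estimated correlation). Among the interferon-stimulated genes, 34 of 36 rose, or 34 adjusted over the list alone, with a median of 2.40 (camera adjusted p = 2.68e-26, and adjusted p = 0.0904 with an estimated correlation). Among the p53 targets, 20 of 32 rose, or 22 adjusted over the list alone (camera adjusted p = 4.22e-09, and adjusted p = 0.0190 with an estimated correlation). NF-kB feedback genes did not pass the list test (camera adjusted p = 0.403), with ICAM1 rising by 1.66 ± 0.12. Among the proteases and growth factors, 17 of 32 rose and 4 fell, or 18 and 5 adjusted over the list alone (camera adjusted p = 4.72e-04, and adjusted p = 0.184 with an estimated correlation). Examples were NRG1 (2.06 ± 0.10) and ANGPTL4 (1.96 ± 0.14). Among the lysosomal genes, 20 of 38 rose and 2 fell, or 21 and 2 adjusted over the list alone (camera adjusted p = 5.05e-06, and adjusted p = 0.325 with an estimated correlation). They included the proton pump subunit ATP6V0A1 (1.30 ± 0.11) and the calcium channel MCOLN1 (0.96 ± 0.11). Among the cholesterol synthesis and uptake genes, 14 of 24 fell and 2 rose, or 15 and 2 adjusted over the list alone (camera adjusted p = 0.00114, and adjusted p = 0.0904 with an estimated correlation). An example was INSIG1 (-1.15 ± 0.11). Without proliferating wild-type replicate 1 or without proliferating wild-type replicate 2 or without senescent knockout replicate 1, 2 protease and growth factor genes were called lower.

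In knockout cells, among the LXR targets other than ABCA1, 6 of 9 rose, or 6 adjusted over the list alone (camera adjusted p = 0.0189, and adjusted p = 0.167 with an estimated correlation). Among the oxidative phosphorylation genes, 7 of 36 fell, or 0 adjusted over the list alone (camera adjusted p = 0.0250, and adjusted p = 0.713 with an estimated correlation). The remaining lists did not pass. Their camera adjusted p was 0.336 for fatty acid synthesis, 0.324 for fibrillar matrix, 0.109 for contractile genes, 0.469 for caveolae, 0.574 for ATF4 targets and 0.469 for the unfolded protein response. Without proliferating wild-type replicate 1 or without proliferating wild-type replicate 2, 3 oxidative phosphorylation genes were called lower. After removal of proliferating knockout replicate 1, 3 LXR target genes were called higher, 23 oxidative phosphorylation genes were called lower and the LXR target list was not called (camera adjusted p = 0.0625). On leaving out proliferating knockout replicate 2, 3 LXR target genes were called higher, 0 oxidative phosphorylation genes were called lower and the oxidative phosphorylation list was not called (camera adjusted p = 0.885). Without senescent wild-type replicate 1 or without senescent wild-type replicate 2, 2 LXR target genes were called higher. Once senescent knockout replicate 1 was removed, 3 LXR target genes were called higher, 0 oxidative phosphorylation genes were called lower and the oxidative phosphorylation list was not called (camera adjusted p = 0.126). Without senescent knockout replicate 2, 2 LXR target genes were called higher, 2 oxidative phosphorylation genes were called lower and the LXR target list was not called (camera adjusted p = 0.0530). Under the replicate block, 1 oxidative phosphorylation gene was called higher and 17 oxidative phosphorylation genes were called lower. The LXR target list was not called with the GC correction and the block (camera adjusted p = 0.0518). The oxidative phosphorylation list was not called with a mean of at least 5 CPM per gene (camera adjusted p = 0.121). In total 5857 genes were called at an edgeR adjusted p under 0.05, 2813 higher and 3044 lower.

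The third comparison asked how the knockout differed from wild-type before bleomycin. Knockout cells had lower MKI67 and MCM2 and higher MX1, IFI6 and ACTA2 transcript. MKI67 was 206 ± 48.0 CPM in knockout against 449.6 ± 38.4 in wild-type cells (-1.13 ± 0.15). Lower values were also measured for KIF20A (-0.93 ± 0.11), FOXM1 (-0.77 ± 0.09), which is a transcription factor of the mitotic program, MCM2 (-0.83 ± 0.11) and HMGB2 (-0.77 ± 0.12). MX1 was higher by 2.73 ± 0.18, IFI6 by 2.14 ± 0.12, ISG15 by 1.95 ± 0.18, XAF1 by 4.09 ± 0.40 and IFIT1 by 1.40 ± 0.17. The smooth muscle actins ACTA2 and ACTG2 were higher by 2.17 ± 0.12 and 1.27 ± 0.11, and the YAP target ANKRD1 by 2.18 ± 0.12. CDKN2A was higher by 1.32 ± 0.14, and CDKN1A stood at 0.21 ± 0.10 (edgeR adjusted p = 0.184).

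Several genes had no or almost no count in the proliferating knockout libraries. No read of CHRDL1, an inhibitor of BMP signaling, was counted there against 9.06 ± 0.723 CPM in wild-type, which makes it at least 202-fold lower, taking 3 counts over the group as the floor. On the same basis the contactin CNTN3 was at least 148-fold, the laminin chain LAMA1 at least 142-fold and TRIM58 at least 127-fold lower. Elastin was also lower, as ELN (-5.79 ± 0.39). In the other direction, the kinase gene NRK was higher by 6.54 ± 0.27, PID1 by 6.15 ± 0.22, CA8 by 4.39 ± 0.15 and FEZ1 by 3.40 ± 0.17. The water channel AQP1 stood at 13.2 ± 0.826 CPM in knockout and 1.16 ± 0.0987 in wild-type cells (edgeR adjusted p = 6.73e-07).

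In proliferating knockout cells, among the mitosis genes, 37 of 43 were lower, or 42 adjusted over the list alone, with a median of -0.61 (camera adjusted p = 5.73e-24, and adjusted p = 0.00451 with an estimated correlation). Among the replication genes, 25 of 40 were lower and 1 was higher, or 35 and 1 adjusted over the list alone (camera adjusted p = 9.01e-14, and adjusted p = 0.0707 with an estimated correlation). Among the nuclear proteins lost in senescence, 9 of 10 were lower, or 9 adjusted over the list alone (camera adjusted p = 7.79e-07, and adjusted p = 0.0523 with an estimated correlation). LMNB1 was lower at -0.61 ± 0.12 but not called without proliferating wild-type replicate 1 (-0.51, edgeR adjusted p = 0.0686). Among the interferon-stimulated genes, 28 of 36 were higher, or 30 adjusted over the list alone (camera adjusted p = 5.73e-24, and adjusted p = 0.0774 with an estimated correlation). Among the contractile and YAP target genes, 13 of 18 were higher and 1 was lower, or 13 and 1 adjusted over the list alone (camera adjusted p = 2.03e-09, and adjusted p = 0.0523 with an estimated correlation). Among the lysosomal genes, 20 of 38 were higher and 0 were lower, or 23 and 1 adjusted over the list alone (camera adjusted p = 4.07e-07, and adjusted p = 0.200 with an estimated correlation). Among the unfolded protein response genes, 12 of 20 were higher, or 13 adjusted over the list alone (camera adjusted p = 5.34e-07, and adjusted p = 0.131 with an estimated correlation). An example was DNAJB9 (0.97 ± 0.10). With proliferating wild-type replicate 1 left out, 3 lysosomal genes and 5 unfolded protein genes were called higher and 8 replication genes and 3 nuclear protein genes were called lower. When proliferating wild-type replicate 2 was left out, 2 lysosomal genes and 1 unfolded protein gene were called higher and 13 replication genes and 5 nuclear protein genes were called lower. After removal of proliferating knockout replicate 2, 12 lysosomal genes were called higher. With the replicate block, 1 lysosomal gene was called lower.

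In the same cells, among the proteases and growth factors, 13 of 32 were higher and 3 were lower, or 16 and 4 adjusted over the list alone (camera adjusted p = 5.62e-04, and adjusted p = 0.159 with an estimated correlation). Examples were ANGPTL4 (2.12 ± 0.15) and IGFBP3 (1.55 ± 0.12) and, with the other sign, SERPINB2 (-1.70 ± 0.10). Among the cholesterol synthesis and uptake genes, 8 of 24 were lower, or 8 adjusted over the list alone (camera adjusted p = 9.67e-04, and adjusted p = 0.0774 with an estimated correlation). An example was INSIG1 (-1.05 ± 0.10). Among the fatty acid synthesis genes, 3 of 14 were lower and 1 was higher, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0306, and adjusted p = 0.461 with an estimated correlation). An example was SCD (-1.36 ± 0.12). Among the fibrillar matrix genes, 12 of 28 were higher and 2 were lower, or 14 and 2 adjusted over the list alone (camera adjusted p = 7.08e-04, and adjusted p = 0.461 with an estimated correlation). They included SPARC (0.88 ± 0.12) and, with the other sign, BGN (-2.34 ± 0.15), a proteoglycan. The median of that list was 0.36 and its mean 0.03. Among the p53 targets, 5 of 32 were higher and 1 was lower, or 10 and 1 adjusted over the list alone (camera adjusted p = 2.21e-04, and adjusted p = 0.0523 with an estimated correlation). An example was SPATA18 (2.36 ± 0.15). Among the NF-kB feedback genes, 4 of 15 were higher and 0 were lower, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.00471, and adjusted p = 0.0774 with an estimated correlation). Among the caveolae genes, 3 of 9 were higher, or 4 adjusted over the list alone (camera adjusted p = 0.0398, and adjusted p = 0.200 with an estimated correlation). For oxidative phosphorylation genes, edgeR called 0 of 36, or 0 adjusted over the list alone, 4 were higher and 0 lower at an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 0, the replicate block with the GC correction 8, and the list was called with a median of 0.17 (camera adjusted p = 0.0141, and adjusted p = 0.659 with an estimated correlation). The cytokine, ATF4 target and LXR target lists did not pass (camera adjusted p = 0.50, 0.697 and 0.432), although IL6 was higher by 1.10 ± 0.11 and CXCL12 lower at -0.95 ± 0.14. On leaving out proliferating wild-type replicate 1, 1 fibrillar matrix gene, 3 p53 target genes, 1 NF-kB feedback gene and 0 caveolae genes were called higher, 3 cholesterol genes were called lower and the oxidative phosphorylation list was not called (camera adjusted p = 0.0873). Once proliferating wild-type replicate 2 was removed, 3 fibrillar matrix genes, 3 p53 target genes, 0 NF-kB feedback genes and 0 caveolae genes were called higher, 5 cholesterol genes were called lower and the caveolae list was not called (camera adjusted p = 0.0922). Without proliferating knockout replicate 1, 20 oxidative phosphorylation genes were called higher, 5 protease and growth factor genes and 5 fatty acid genes were called lower and the fibrillar matrix and caveolae lists were not called (camera adjusted p = 0.0516 and 0.0741). With proliferating knockout replicate 2 left out, 8 p53 target genes were called higher, the fatty acid and caveolae lists were not called (camera adjusted p = 0.155 and 0.0748) and the median of the oxidative phosphorylation list turned to -0.0259 and the list was not called (camera adjusted p = 0.514). Under the replicate block, 2 fatty acid genes, 11 p53 target genes and 5 oxidative phosphorylation genes were called higher and 5 protease and growth factor genes and 6 fatty acid genes were called lower. The caveolae list was not called with library totals alone (camera adjusted p = 0.0650), with a mean of at least 5 CPM per gene (camera adjusted p = 0.0521), with the GC correction and the block (camera adjusted p = 0.0618) and with the GC correction (camera adjusted p = 0.0847). The oxidative phosphorylation list was not called with library totals alone (camera adjusted p = 0.0510).

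In total 2308 genes differed between the proliferating genotypes at an edgeR adjusted p under 0.05, 1259 higher and 1049 lower in the knockout. The count was 942 without proliferating wild-type replicate 1, 934 without proliferating wild-type replicate 2, 4087 without proliferating knockout replicate 1 and 3708 with the replicate number as a block. Library totals alone split the calls as 846 higher and 1584 lower.

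The fourth comparison asked how the knockout differed from wild-type after bleomycin. Knockout cells had lower IL1B, IL6, CXCL8 and MKI67 transcript. IL1B was 1.30 ± 0.0204 CPM in senescent knockout against 23.5 ± 2.77 in senescent wild-type cells (-4.17 ± 0.21). IL6 was 42.8 ± 2.46 against 151 ± 8.10 CPM (-1.82 ± 0.11) and CXCL8 10.0 ± 0.597 against 75.6 ± 15.6 CPM (-2.92 ± 0.15). Lower values, as knockout minus wild-type, were also measured for CSF2 (-3.36 ± 0.25), IL1A (-2.54 ± 0.18) and CCL2 (-1.71 ± 0.22). The p53 target CDKN1A stood at -0.18 ± 0.10 (edgeR adjusted p = 0.257) and MDM2 at -0.00409 ± 0.10 (edgeR adjusted p = 0.984). With the GC correction and the replicate block, CDKN1A was called at -0.26 (edgeR adjusted p = 0.0184). GDF15, a secreted p53 target, was lower at -1.94 ± 0.15. CDK1 was lower at -2.95 ± 0.13, CDC20 at -2.58 ± 0.12, MKI67 at -2.69 ± 0.17, RRM2 at -2.46 ± 0.12 and LMNB1 at -2.37 ± 0.15. CDKN2A was higher at 0.97 ± 0.13.

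In senescent knockout cells, among the cytokines and chemokines, 13 of 17 were lower, or 15 adjusted over the list alone, with a median of -1.46 (camera adjusted p = 4.67e-10, and adjusted p = 0.0365 with an estimated correlation). Among the NF-kB feedback genes, 12 of 15 were lower, or 13 adjusted over the list alone (camera adjusted p = 5.23e-09, and adjusted p = 0.0260 with an estimated correlation). Examples were ICAM1 (-1.69 ± 0.12), TNFAIP3 (-1.66 ± 0.13) and BIRC3 (-1.65 ± 0.13). Among the ATF4 targets, 17 of 28 were lower and 0 were higher, or 17 and 2 adjusted over the list alone (camera adjusted p = 7.48e-07, and adjusted p = 0.0267 with an estimated correlation). They included the lipoprotein receptor VLDLR (-2.53 ± 0.18), DDIT4 (-1.80 ± 0.12) and the serine synthesis enzyme PHGDH (-1.43 ± 0.11). Among the mitosis genes, 42 of 43 were lower, or 43 adjusted over the list alone (camera adjusted p = 3.26e-49, and adjusted p = 0.00104 with an estimated correlation). Among the replication genes, 34 of 40 were lower and 1 was higher, or 35 and 1 adjusted over the list alone (camera adjusted p = 3.00e-23, and adjusted p = 0.0343 with an estimated correlation). Among the nuclear proteins lost in senescence, 7 of 10 were lower, or 9 adjusted over the list alone (camera adjusted p = 6.50e-07, and adjusted p = 0.0365 with an estimated correlation). Among the contractile and YAP target genes, 10 of 18 were higher and 0 were lower, or 11 and 1 adjusted over the list alone (camera adjusted p = 6.50e-07, and adjusted p = 0.0365 with an estimated correlation). They included ANKRD1 (1.49 ± 0.12), ACTA2 (1.17 ± 0.12) and CALD1 (0.93 ± 0.11). Without senescent wild-type replicate 2 or without senescent knockout replicate 2, 6 contractile genes were called higher. With the replicate block, 2 ATF4 target genes were called higher and 1 contractile gene was called lower.

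Among the fibrillar matrix genes, 10 of 28 were lower, or 11 adjusted over the list alone (camera adjusted p = 2.66e-04, and adjusted p = 0.612 with an estimated correlation). Examples were ELN (-4.24 ± 0.30), BGN (-3.23 ± 0.14) and LUM (-1.19 ± 0.11). Among the interferon-stimulated genes, 10 of 36 were lower and 0 were higher, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.0200, and adjusted p = 0.701 with an estimated correlation). They included CXCL10 (-1.67 ± 0.15) and BST2 (-1.12 ± 0.14). IFIT1 stood at -0.14 ± 0.16 (edgeR adjusted p = 0.581). Other lists did not pass the test. Among proteases and growth factors (camera adjusted p = 0.0757), VEGFA was lower at -1.09 ± 0.13 and STC1 at -1.24 ± 0.12. MMP3 stood at 0.20 ± 0.15 (edgeR adjusted p = 0.414). Among lysosomal genes (camera adjusted p = 0.0744), CTSK was lower at -1.05 ± 0.10 and MCOLN1 higher at 0.83 ± 0.11. In the cholesterol list (camera adjusted p = 0.412), INSIG1 was lower at -0.89 ± 0.11. SCD was lower at -1.46 ± 0.13 within the fatty acid list (camera adjusted p = 0.611) and APOE at -2.64 ± 0.24 within the LXR list (camera adjusted p = 0.978). The camera adjusted p was 0.685 for p53 targets, 0.404 for caveolae, 0.611 for the unfolded protein response and 0.891 for oxidative phosphorylation. Signs differed within 4 of these uncalled lists. The LXR list had a median of -0.13 and a mean of -0.28 and the oxidative phosphorylation list -0.02 and -0.03, both with a test of positive sign. The p53 list had a median of -0.03 and a mean of 0.01, and the fatty acid list 0.03 and -0.03, again with tests of positive sign. When senescent wild-type replicate 1 was left out, 5 fibrillar matrix genes were called lower and the lysosomal list was called (camera adjusted p = 0.00270). After removal of senescent wild-type replicate 2, 5 interferon-stimulated genes were called lower, the interferon-stimulated list was not called (camera adjusted p = 0.503) and the protease and growth factor list was called (camera adjusted p = 0.00989). On leaving out senescent knockout replicate 1, the interferon-stimulated list was not called (camera adjusted p = 0.0926). Once senescent knockout replicate 2 was removed, 5 fibrillar matrix genes and 6 interferon-stimulated genes were called lower and the lysosomal list was called (camera adjusted p = 0.0458). Under the replicate block, 2 fibrillar matrix genes and 2 interferon-stimulated genes were called higher. The interferon-stimulated list was not called with a mean of at least 5 CPM per gene (camera adjusted p = 0.0575). The protease and growth factor list was called with the GC correction and the block (camera adjusted p = 0.0436) and with the GC correction (camera adjusted p = 0.0428). The lysosomal list was called with a mean of at least 5 CPM per gene (camera adjusted p = 0.0387).

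Some genes near the floor before bleomycin were also near it after. CNTN3 had no count in the senescent knockout libraries and was at least 219-fold lower than in wild-type cells. PTGIS, the prostacyclin synthase, had 3 counts over both knockout libraries, a ratio of wild-type to knockout of 265 with a 95% Clopper-Pearson counting interval of 90.4 to 1289. CHRDL1 also had 3 counts, a ratio of 136 (46.3 to 663). The tetraspanin TSPAN2 was lower at -6.26 ± 0.30. NRK, CA8, the cyclin CCND2 and LRP3 were higher by 5.84 ± 0.21, 3.82 ± 0.14, 3.19 ± 0.19 and 2.76 ± 0.17. In total 2730 genes differed between the senescent genotypes, 926 higher and 1804 lower in the knockout (edgeR adjusted p under 0.05). The count was 1684 without senescent wild-type replicate 1, 1299 without senescent wild-type replicate 2, 1790 without senescent knockout replicate 1 and 1590 without senescent knockout replicate 2.

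**Figure D2:**
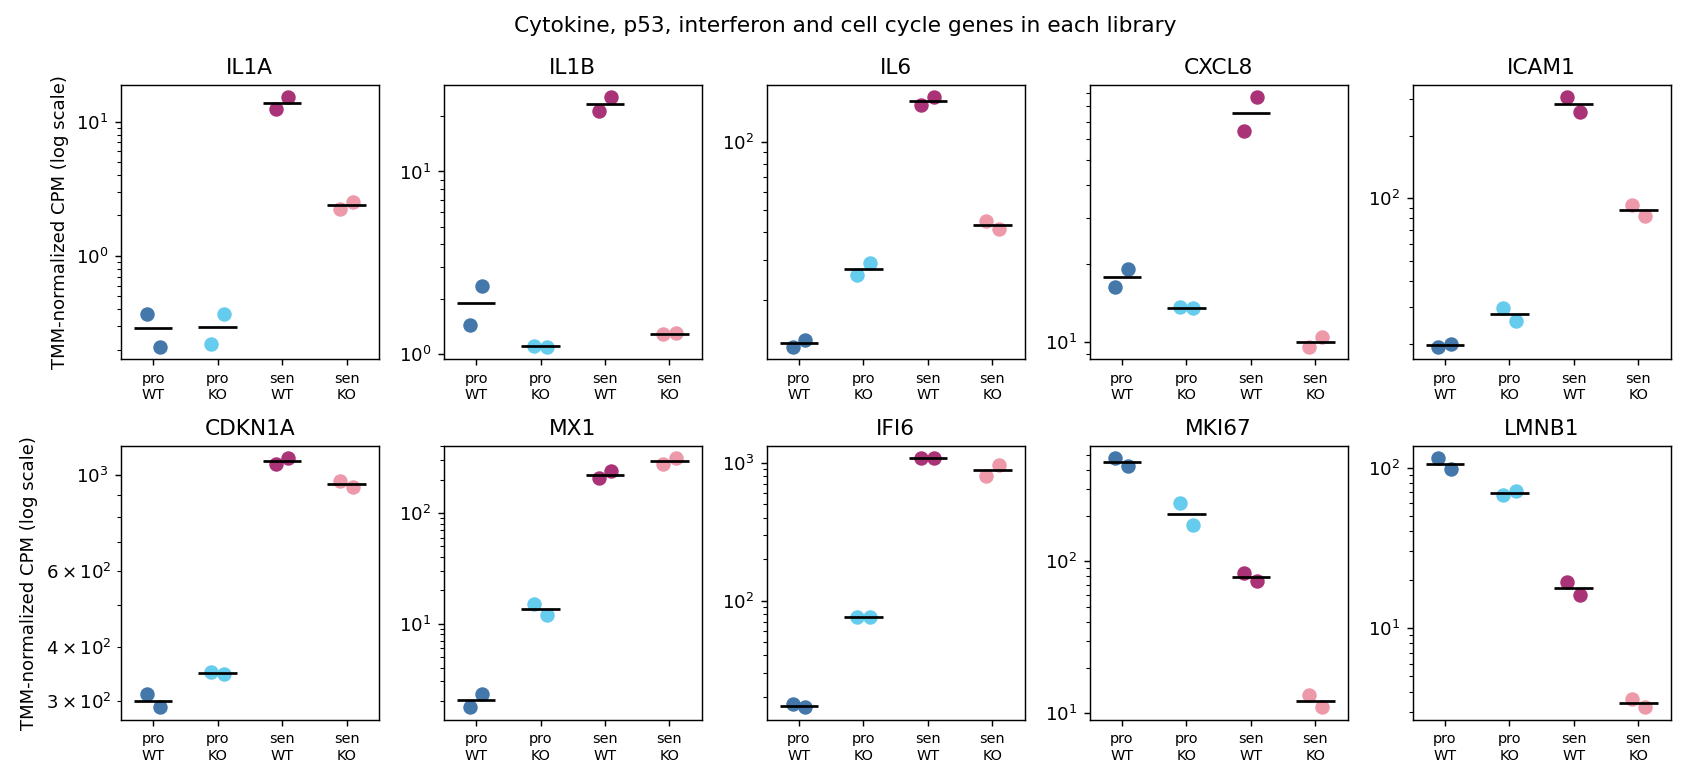
TMM-normalized CPM on a log axis (y axis) of 10 genes in the proliferating (pro) and senescent (sen), wild-type (WT) and knockout (KO) libraries (x axis); points are libraries and lines group means. IL1B reached 23.5 CPM on average in senescent wild-type and 1.30 in senescent knockout libraries, while CDKN1A reached 1079.6 and 954.

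The interaction term asked directly whether the bleomycin response differed between the genotypes. Negative values mark a lower log2 change after bleomycin in knockout than in wild-type cells. IL6 gave -2.91 ± 0.15 (edgeR adjusted p = 6.36e-06), CXCL8 -2.53 ± 0.21, IL1B -3.39 ± 0.36, CSF2 -4.55 ± 0.56 and ICAM1 -2.18 ± 0.17. For CSF2 the estimate was -3.84 without proliferating knockout replicate 2. IL1A gave -2.58 ± 0.56 and CCL2 gave -2.11 ± 0.40. IL1A was not called without proliferating wild-type replicate 2 (edgeR adjusted p = 0.0881) or proliferating knockout replicate 2 (edgeR adjusted p = 0.162), and CCL2 was not called without proliferating wild-type replicate 1 (edgeR adjusted p = 0.0535). INSIG1 stood at 0.16 ± 0.15 and MDM2 at -0.15 ± 0.14 (edgeR adjusted p = 0.638 and 0.614). CDKN1A stood at -0.39 ± 0.14 (edgeR adjusted p = 0.161) and was called with the replicate number as a block (edgeR adjusted p = 0.0367) and with that block plus the GC correction (edgeR adjusted p = 0.0125).

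In the interaction, among the cytokines and chemokines, 10 of 17 were negative, or 10 adjusted over the list alone (camera adjusted p = 1.76e-11, and adjusted p = 0.0512 with an estimated correlation). Among the NF-kB feedback genes, 11 of 15 were negative, or 13 adjusted over the list alone (camera adjusted p = 8.47e-13, and adjusted p = 0.0125 with an estimated correlation). Examples were BIRC3 (-1.86 ± 0.19) and SOD2 (-1.59 ± 0.16). Among the mitosis genes, 35 of 43 were negative, or 36 adjusted over the list alone (camera adjusted p = 5.86e-43, and adjusted p = 0.00137 with an estimated correlation). They included CDK1 (-2.45 ± 0.17) and HMMR (-2.15 ± 0.17). Among the interferon-stimulated genes, 25 of 36 were negative, or 33 adjusted over the list alone (camera adjusted p = 1.70e-29, and adjusted p = 0.0743 with an estimated correlation). Named members were XAF1 (-3.60 ± 0.46), BST2 (-3.42 ± 0.32) and IFI6 (-2.43 ± 0.16). The knockout started higher for IFI6, which went from 17.2 ± 0.640 to 1079 ± 2.61 CPM in wild-type and from 75.8 ± 0.590 to 883 ± 109 in knockout cells. Among the ATF4 targets, 10 of 28 were negative and 1 was positive, or 17 and 1 adjusted over the list alone (camera adjusted p = 2.96e-08, and adjusted p = 0.0180 with an estimated correlation). Among them were CHAC1 (-1.39 ± 0.15), ATF3 (-1.35 ± 0.18) and DDIT4 (-1.27 ± 0.17) and, with the other sign, SLC7A11 (1.16 ± 0.21), a cystine transporter. Among the replication genes, 12 of 40 were negative, or 18 adjusted over the list alone (camera adjusted p = 7.08e-10, and adjusted p = 0.0801 with an estimated correlation). Among the proteases and growth factors, 12 of 32 were negative and 1 was positive, or 15 and 1 adjusted over the list alone (camera adjusted p = 9.94e-07, and adjusted p = 0.0801 with an estimated correlation). Examples were IGFBP3 (-2.05 ± 0.17) and ANGPTL4 (-2.03 ± 0.19). Among the fibrillar matrix genes, 13 of 28 were negative, or 20 adjusted over the list alone (camera adjusted p = 1.30e-09, and adjusted p = 0.195 with an estimated correlation). They included LUM (-1.68 ± 0.15) and DCN (-1.05 ± 0.16). Without proliferating wild-type replicate 1, 6 cytokine genes, 4 ATF4 target genes, 7 replication genes and 4 fibrillar matrix genes were called negative. With proliferating wild-type replicate 2 left out, 7 replication genes, 6 protease and growth factor genes and 2 fibrillar matrix genes were called negative. When senescent wild-type replicate 1 was left out, 4 fibrillar matrix genes were called negative. After removal of senescent knockout replicate 1, 5 fibrillar matrix genes were called negative. On leaving out senescent knockout replicate 2, 6 fibrillar matrix genes were called negative. With the replicate block, 21 fibrillar matrix genes were called negative.

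Shifts were also called in the interaction for 6 other lists. Among the unfolded protein response genes, 5 of 20 were negative, or 11 adjusted over the list alone, with a median of -0.48 (camera adjusted p = 7.54e-05, and adjusted p = 0.193 with an estimated correlation). Among the p53 targets, 1 of 32 was negative, or 4 adjusted over the list alone, with a median of -0.29 (camera adjusted p = 9.33e-04, and adjusted p = 0.0594 with an estimated correlation). Among the lysosomal genes, 2 of 38 were negative, or 2 adjusted over the list alone, with a median of -0.25 (camera adjusted p = 0.00617, and adjusted p = 0.431 with an estimated correlation). Among the contractile and YAP target genes, 3 of 18 were negative, or 6 adjusted over the list alone, with a median of -0.25 (camera adjusted p = 0.0172, and adjusted p = 0.193 with an estimated correlation). Among the fatty acid synthesis genes, 1 of 14 was positive, or 3 adjusted over the list alone, with a median of 0.21 (camera adjusted p = 0.0172, and adjusted p = 0.408 with an estimated correlation). For cholesterol synthesis and uptake, edgeR called 0 of 24, or 0 adjusted over the list alone, 3 were positive and 1 negative at an unadjusted p under 0.05, DESeq2 called 0 and limma-voom 0, the replicate block with the GC correction 3, with a list median of 0.10 (camera adjusted p = 0.00936, and adjusted p = 0.115 with an estimated correlation). Not called were nuclear proteins lost in senescence, LXR targets, caveolae and oxidative phosphorylation (camera adjusted p = 0.0697, 0.354, 0.359 and 0.0697). Once proliferating wild-type replicate 1 was removed, 1 unfolded protein gene and 0 contractile genes were called negative and the nuclear protein list was called (camera adjusted p = 0.0368). Without proliferating wild-type replicate 2, 2 unfolded protein genes and 1 contractile gene were called negative and the lysosomal and contractile lists were not called (camera adjusted p = 0.0542 and 0.0821). With proliferating knockout replicate 1 left out, 3 fatty acid genes were called positive, 9 unfolded protein genes, 7 p53 target genes, 10 lysosomal genes and 7 contractile genes were called negative, the cholesterol list was not called (camera adjusted p = 0.0842) and the oxidative phosphorylation list was called (camera adjusted p = 8.96e-06). When proliferating knockout replicate 2 was left out, the fatty acid list was not called (camera adjusted p = 0.101). After removal of senescent wild-type replicate 1, 2 unfolded protein genes were called negative, the lysosomal and contractile lists were not called (camera adjusted p = 0.134 and 0.0575) and the oxidative phosphorylation list was called (camera adjusted p = 0.00541). On leaving out senescent wild-type replicate 2, 3 unfolded protein genes and 1 contractile gene were called negative and the fatty acid list was not called (camera adjusted p = 0.0914). Once senescent knockout replicate 1 was removed, 2 unfolded protein genes and 1 contractile gene were called negative, the fatty acid list was not called (camera adjusted p = 0.0533) and the nuclear protein list was called (camera adjusted p = 0.0407). Without senescent knockout replicate 2, 2 unfolded protein genes and 1 contractile gene were called negative and the oxidative phosphorylation list was called (camera adjusted p = 0.0273). Under the replicate block, 1 lysosomal gene, 3 fatty acid genes and 2 cholesterol genes were called positive, 11 unfolded protein genes, 7 p53 target genes, 9 lysosomal genes and 6 contractile genes were called negative and the oxidative phosphorylation list was called (camera adjusted p = 0.0174). The contractile list was not called with library totals alone (camera adjusted p = 0.0506). The oxidative phosphorylation list was called by camera on ranks (camera adjusted p = 0.0156) and with the GC correction and the block (camera adjusted p = 0.0199).

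In all, 794 genes were called in the interaction at an edgeR adjusted p under 0.05, 90 positive and 704 negative. Of these, 477 had risen in wild-type cells with a negative interaction, and 166 had fallen in wild-type cells with a negative interaction. Another 59 had fallen and 5 had risen with a positive interaction, and 87 were not called in wild-type cells. The count was 383 without proliferating wild-type replicate 1, 412 without proliferating wild-type replicate 2, 2109 without proliferating knockout replicate 1, 523 without senescent wild-type replicate 1, 473 without senescent wild-type replicate 2, 527 without senescent knockout replicate 1 and 1697 with the replicate number as a block. Scaling by library totals alone moved the median of all genes by 0.13 and gave 179 positive and 476 negative.

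**Figure D3:**
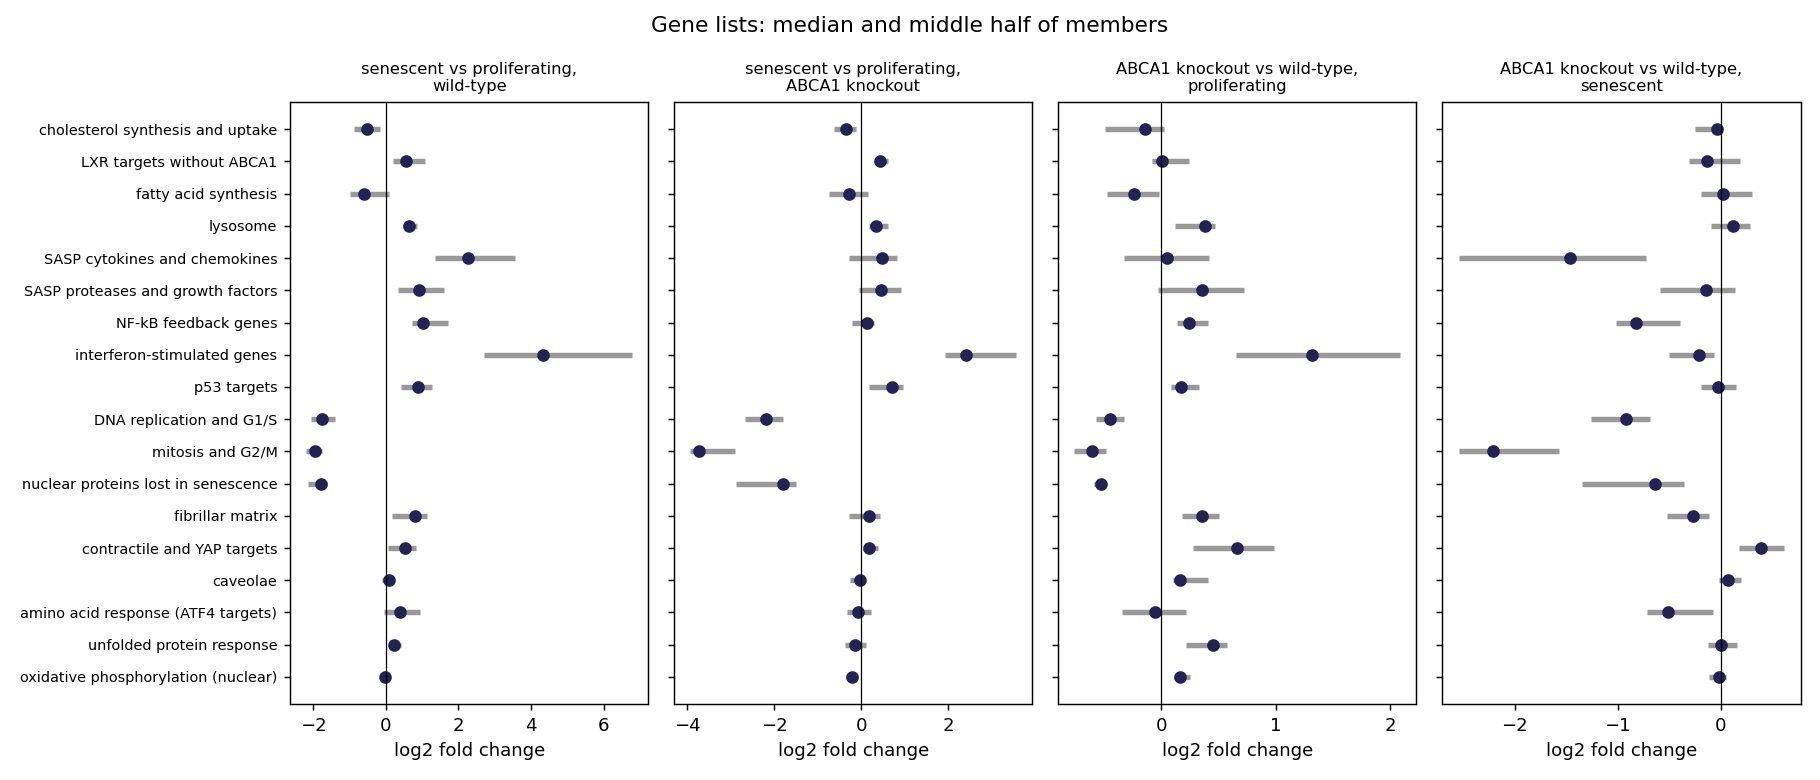
Median log2 fold change (points) and interquartile range of members (bars) of the 18 gene lists (y axis) in 4 comparisons (panels, each with its own x axis scale). The cytokine list has a median of 2.28 in wild-type and 0.48 in knockout cells after bleomycin, and the mitosis list of -1.94 and -3.71.

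Across the 14392 genes, log2 fold changes after bleomycin in wild-type and in knockout cells, which share no library, correlated with Pearson r = 0.73 and Spearman rho = 0.76. Genes are not independent replicates. Both genotypes shared 2141 called rises, where independent lists would share 704, and 2144 called falls, where independent lists would share 652. There were 73 genes called in opposite directions. The genotype differences before and after bleomycin gave r = 0.61 and rho = 0.42 across the same genes. They shared 403 genes higher in the knockout in both states (81.0 for independent lists) and 660 lower in both (131), with 119 in opposite directions.

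Library composition moved with bleomycin as well. Ribosomal protein genes took 3.20% ± 0.243 of counts in proliferating wild-type, 3.22% ± 0.696 in proliferating knockout, 2.45% ± 0.305 in senescent wild-type and 2.05% ± 0.145 in senescent knockout libraries (SD, n = 2 each). The 4 senescent libraries lay below the 4 proliferating ones (two-sided exact permutation p = 0.0286 for bleomycin, 0.0457 adjusted by Benjamini-Hochberg). The first of these is the smallest p this design allows, and 8 measures were compared for bleomycin and for genotype, 16 tests in all. Mitochondrially encoded genes took 3.88% ± 0.0955, 3.82% ± 0.0843, 2.99% ± 0.174 and 3.78% ± 0.377 of counts in the same order (exact permutation p = 0.143 for bleomycin, 0.143 adjusted). The 10 most abundant genes took between 7.34% and 9.58% of a library. Summed fibroblast markers, mostly COL1A1, COL1A2 and VIM, were 22686, 27870.0, 36640.0 and 31640.0 CPM in that order (exact permutation p = 0.0286 for bleomycin, 0.0457 adjusted). Leukocyte markers summed to 54.5, 50.7, 98.1 and 70.2 CPM, mostly the lysosomal protein CD68 (exact permutation p = 0.0286 for bleomycin, 0.0457 adjusted). Endothelial markers summed to 52.7, 85.6, 147 and 140.0 CPM, mostly TEK (exact permutation p = 0.0286 for bleomycin, 0.0457 adjusted). Epithelial markers, mostly KRT8 and KRT18, summed to 206, 167, 172 and 129 CPM (exact permutation p = 0.114 for bleomycin, 0.131 adjusted). For genotype, the 8 adjusted p lay between 0.686 and 1 by the same exact permutation tests, which pool both states. With libraries exchanged only within the other factor, a restriction chosen after seeing the data, no two-sided exact permutation p can be below 0.0556, or below 0.125 when same-numbered libraries are also paired, so 0.05 cannot be reached. Epithelial and leukocyte markers were lower in both knockout libraries than in both wild-type libraries of each state and gave this smallest p, 0.0556, for genotype, while the other 6 measures gave 0.278 to 1. For bleomycin 6 of the 8 measures gave 0.0556 under the same restriction, the mitochondrial share 0.167 and the 10 most abundant genes 0.111. The ribosomal protein share was higher in replicate 2 than in replicate 1 in 4 of 4 groups, and the mitochondrial share, that of the 10 most abundant genes and the endothelial and fibroblast sums were lower in replicate 2 in 4 of 4. Epithelial sums were higher there in 3 groups and leukocyte sums in 1. PTPRC and LYZ of leukocytes stayed at or below 0.140 CPM on average in every group, and EPCAM of epithelium at or below 0.242.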

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

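The tests set against explanations in this part, except that of replicate differences without GC and length trends, and the GC corrections were chosen after the results were seen, while the interaction tests were planned. The bleomycin response differed between wild-type and knockout cells, by the test of the interaction, for 794 genes, for 14 gene lists and for the genes below. The median interaction of a list, on the log2 scale, was -1.76 for cytokines and chemokines, -1.64 for interferon-stimulated genes, -1.50 for mitosis, -1.11 for NF-kB feedback, -0.68 for fibrillar matrix, -0.58 for proteases and growth factors, -0.48 for ATF4 targets, -0.48 for the unfolded protein response, -0.41 for replication, -0.29 for p53 targets, -0.25 for lysosome, -0.25 for contractile genes, 0.21 for fatty acid synthesis and 0.10 for cholesterol synthesis and uptake. Of these lists, mitosis, NF-kB feedback and ATF4 targets kept an adjusted p under 0.05 with an estimated correlation, and the other 11 gave 0.0512 to 0.431. Median knockout minus wild-type differences before and after bleomycin were 1.32 and -0.22 for interferon-stimulated genes and 0.45 and 0.0007 for the unfolded protein response. They were 0.05 and -1.46 for cytokines, so a negative value need not mean a lower level after bleomycin. The count of genes moved without 1 library, as given above, and was 1697 with the replicate block. With proliferating wild-type replicate 1 left out, the nuclear protein list was called (camera adjusted p = 0.0368). When proliferating wild-type replicate 2 was left out, the lysosomal and contractile lists were not called (camera adjusted p = 0.0542 and 0.0821). After removal of proliferating knockout replicate 1, the cholesterol list was not called (camera adjusted p = 0.0842) and the oxidative phosphorylation list was called (camera adjusted p = 8.96e-06). On leaving out proliferating knockout replicate 2, the fatty acid list was not called (camera adjusted p = 0.101). Once senescent wild-type replicate 1 was removed, the lysosomal and contractile lists were not called (camera adjusted p = 0.134 and 0.0575) and the oxidative phosphorylation list was called (camera adjusted p = 0.00541). Without senescent wild-type replicate 2, the fatty acid list was not called (camera adjusted p = 0.0914). With senescent knockout replicate 1 left out, the fatty acid list was not called (camera adjusted p = 0.0533) and the nuclear protein list was called (camera adjusted p = 0.0407). When senescent knockout replicate 2 was left out, the oxidative phosphorylation list was called (camera adjusted p = 0.0273). With the replicate block, the oxidative phosphorylation list was called (camera adjusted p = 0.0174). The contractile list was not called with library totals alone (camera adjusted p = 0.0506). The oxidative phosphorylation list was called by camera on ranks (camera adjusted p = 0.0156) and with the GC correction and the block (camera adjusted p = 0.0199).

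Genes with a negative interaction were CSF2 (-4.55), XAF1 (-3.60), BST2 (-3.42), IL1B (-3.39), CXCL10 (-3.32), IL6 (-2.91), IL1A (-2.58), CXCL8 (-2.53), CDK1 (-2.45), IFI6 (-2.43), ICAM1 (-2.18), HMMR (-2.15), CCL2 (-2.11), IGFBP3 (-2.05), ANGPTL4 (-2.03), BIRC3 (-1.86), LMNB1 (-1.76), LUM (-1.68), SOD2 (-1.59), MKI67 (-1.56), IFIT1 (-1.54), CHAC1 (-1.39), ATF3 (-1.35), DDIT4 (-1.27) and DCN (-1.05). Genes with a positive interaction were IL21R (2.35), ID1 (2.28), ID2 (1.93), SLC7A11 (1.16) and SERPINB2 (0.90). Without proliferating knockout replicate 2 the CSF2 value was -3.84. IL1A was not called without proliferating wild-type replicate 2 (edgeR adjusted p = 0.0881) or proliferating knockout replicate 2 (edgeR adjusted p = 0.162), and CCL2 was not called without proliferating wild-type replicate 1 (edgeR adjusted p = 0.0535).

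For the negative interaction of cytokines, removing a GC trend from each library, without the block, left 10 of 17 genes called lower. The median was -1.78 against -1.76 uncorrected, which argues against GC content as the whole cause. Ratios of knockout to wild-type log2 rises do not show a response weaker by 1 factor for every gene group. The median was 0.182 (interquartile range 0.0862 to 0.421) for the cytokines that rose in wild-type cells and 0.756 (0.581 to 0.816) for p53 targets. Slopes over all members, risen or not, were 0.301 and 0.736. The cytokine range overlapped those of 8 of 10 other lists, all but p53 targets and interferon-stimulated genes. A negative interaction was not particular to cytokines (NF-kB feedback, -1.11). Leukocytes in the senescent wild-type cultures are argued against by the highest mean of PTPRC, LYZ, TYROBP and LST1 there, 0.132 CPM, next to 23.5 CPM of IL1B. An effect of losing ABCA1, and a difference of the knockout cells unrelated to ABCA1, stay open, since the labels do not say whether the knockout is a clone or a pool and name no rescue.

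Lower mitosis genes in proliferating knockout cells were weighed in the same way: in the GC-corrected fit with the block 41 of 43 were called lower, which argues against GC content as the whole cause. A share of RNA from cells like the measured senescent ones would have to be the same for every gene group, and p53 targets, compared first, gave 17.7% (interquartile range 6.99% to 28.5%) against 46.5% (interquartile range 42.3% to 53.5%) for mitosis with the wild-type senescent profile, but with the knockout profile 21.1% (interquartile range 8.41% to 32.2%) and 37.3% (interquartile range 31.0% to 42.5%), which overlap and did not separate them. Interferon-stimulated genes gave 7.60% (interquartile range 5.01% to 11.5%) and 10.4% (interquartile range 5.91% to 15.3%), below the mitosis ranges with both profiles. That list was chosen after p53 targets did not separate, so such a share stays open. Cytokines gave 1.54% (interquartile range -2.92% to 10.1%) and 27.7% (interquartile range -0.360% to 44.2%), the second of which overlaps with mitosis too. A slower cycle of the knockout cells, their passage or clonal origin, or a denser culture at harvest stays open and was not tested.

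Libraries with the same replicate number deviated together. With trends on GC content and transcript length removed, all 6 pairs of groups kept a correlation over 0.1, from 0.21 to 0.57, so these trends are not the whole of the shared difference. The GC trend of the replicate difference, as Spearman rho across genes, was -0.23 and -0.22 in wild-type cells. In knockout cells it was 0.31 and 0.51, a sign change that the replicate block does not model. A shared day of culture or library preparation stays open, since the labels give no dates, and no biological explanation was tested.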

How the results depend on the processing

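GC corrections, the split of simulated genes by level, the restricted composition tests, and holding the tested genes fixed without 1 library, were chosen after seeing the data, and the other alternatives before. All 5 counts of called genes stayed within 1.5 times of their main value under DESeq2, limma-voom, the legacy dispersion, the other scalings, both filters, removal of mitochondrially encoded genes and the GC correction without a block. In the order wild-type response, knockout response, genotypes in proliferating cells, genotypes in senescent cells and interaction, an absolute log2 fold change of at least 1 left 2134, 1713, 609, 932 and 428 genes, a smaller set by construction, and an adjusted p under 0.01 left 3729, 1108, 1519 and 450 in the last 4. Only the groups compared gave 1411 for the genotypes in proliferating cells. The replicate block gave 3708 there and 1697 in the interaction, keeping 2307 and 792 of the genes called without it. With the GC correction and the replicate block, the last 3 counts were 4311, 4283 and 2184; the cause was not tested. Leaving out 1 library, with the lone sample of its group assumed to vary like the others, gave 4700 to 7742, 4250 to 6557, 934 to 4087, 1299 to 3918 and 383 to 2109 in the same order. The correlation of both bleomycin responses was 0.81 with at least 5 CPM, which leaves fewer genes, and 0.68 to 0.72 without 1 library, and that of both genotype differences 0.50 and 0.56 to 0.61.

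Of 2355 values for the 220 pairs of gene and comparison under planned settings with all libraries, 2331 kept direction and side of the threshold, 13 lost and 11 gained a call, and without 1 library 1721 of 1760 kept them, 33 lost and 6 gained. These genes were chosen for the text after their stability was seen, so the shares kept cannot stand for other genes. The replicate block gained 3 gene calls (MMP1 in the wild-type response, NPC1 between senescent genotypes and CDKN1A in the interaction) and 1 list call, the interaction of oxidative phosphorylation genes (camera adjusted p = 0.0174), and changed no other call of a named gene or list reported here. Of 180 counts of called list members, by direction, 44 moved by over 1.5 times with the block, 16 with the GC correction, 56 with both and 19 to 40 without 1 library. An estimated correlation ended most list calls, 43. Counting uncalled tests, the other planned settings kept 515 of 540, lost 15 and gained 10 calls. Under fry, which does not compare a list with other genes, the lists that lost their call were, with adjusted p, oxidative phosphorylation (0.293) in the knockout response; fatty acid (0.149), fibrillar matrix (0.240) and oxidative phosphorylation (0.384) between proliferating genotypes; interferon-stimulated (0.171) between senescent genotypes; cholesterol (0.0959), fatty acid (0.274) and lysosomal (0.0547) in the interaction, and lists newly called were NF-kB feedback (0.00162), contractile (0.00840) and ATF4 target (0.0477) in the knockout response; cholesterol (0.0313) and protease and growth factor (0.0153) between senescent genotypes; LXR target (0.0209) and nuclear protein (0.00400) in the interaction. Without proliferating knockout replicate 2 the direction of oxidative phosphorylation genes between proliferating genotypes turned, with a median of -0.0259 (camera adjusted p = 0.514), and over the libraries left out that median ran from -0.0259 to 0.35. With depths of 28160545 counts or more and 14392 simulated genes, 2-fold changes in the wild-type response were recovered for 1 of 8 genes under 1 CPM and 48 of 59 others, and in the interaction for 0 of 13 and 35 of 54. Exchanging libraries only within the other factor ended 5 composition calls for bleomycin, since 0.05 cannot be reached there.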

Other observations

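The chromosome test and the selection rule in this part were chosen after the values were seen. TERT, whose counts cannot separate the introduced hTERT from the cell's own gene, fell after bleomycin in wild-type cells from 486 ± 67.6 to 165 ± 20.6 CPM (log2 fold change -1.56 ± 0.21, edgeR adjusted p = 1.56e-04) and in knockout cells from 282 ± 102 to 151 ± 6.50 (-0.90 ± 0.21, edgeR adjusted p = 0.00599). ID2, an inhibitor of bHLH transcription factors like ID1, went from 77.0 ± 2.97 to 12.5 ± 0.0286 CPM in wild-type and from 57.4 ± 1.80 to 35.5 ± 3.14 in knockout cells, and IL21R, a cytokine receptor, from 4.98 ± 0.592 to 2.03 ± 0.328 and from 3.22 ± 0.153 to 6.62 ± 0.970. LUM, a matrix proteoglycan, rose in wild-type cells from 22.5 ± 1.69 to 57.4 ± 2.90 CPM, while in knockout cells it was 31.7 ± 0.346 before and 25.2 ± 1.82 after bleomycin.

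With a mean of at least 5 CPM in both wild-type groups and under 0.25 in both knockout groups, 5 genes were on in wild-type and nearly silent in knockout cells: ANK3, LAMA1, CNTN3, TRIM55 and CHRDL1, on 5 chromosomes, and 0 genes met the mirror rule. Autosome medians of the log2 genotype difference lay no farther from 0 than -0.13 in either state. This is far from the size a lost or gained autosome would give. X, with CHRDL1, and parts of chromosomes were not tested, and such medians say little of single genes. Silencing or clonal selection of such genes, and any link to ABCA1, was not tested.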
